A study of Mus musculus with 13 samples.

How the data were processed

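The study sequenced small RNAs of testes from mice at postnatal day 0, each library made from the pooled testes of 3 males. Exd1+/- and Exd1-/- mice on a mixed C57BL/6;129S4/SvJae background gave 11 libraries. The piRNAs bound to MILI were immunoprecipitated with a mouse monoclonal antibody and those bound to MIWI2 with a rabbit polyclonal antibody, with 2 libraries per genotype and antibody from different pools. Total small RNA between about 15 and 40 nt was taken from a gel for 1 Exd1+/- and 2 Exd1-/- libraries. Testes of Rosa26-pi reporter mice gave 1 MILI and 1 MIWI2 immunoprecipitate (IP). The Exd1-/- allele carries a stop codon cassette in exon 8. The reporter is a DsRed2 coding sequence with a 3′ UTR built on LacZ that holds binding sites for 35 MILI-bound piRNAs, inserted into the Rosa26 locus.

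Per the labels, adapters were removed with cutadapt and reads were aligned with Bowtie to the mouse genome build mm9; the versions and settings are not given in the sources used here. The authors deposited one table of raw read counts for the 11 Exd1 libraries, with 1 line for each of 38195851 distinct sequences of 12 to 51 nt. Each line gives the number of genome positions of the sequence, 1 of these positions, and 1 annotation, which is a repeat family, miRNA, other noncoding RNA, gene exon or gene intron with its strand, or none. How that position was chosen for sequences with several, and whether mismatches were allowed, is not stated. For the reporter libraries the authors deposited Bowtie alignments to the reporter, 1 per line, with 95639 lines for MILI and 175364 for MIWI2. The total depth of the reporter libraries is not given, and the reporter reference sequence was not used here. All coordinates are on mm9 and none were converted. Replicates were not pooled.

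The analysis plan, with the comparisons, lists, named features and most alternatives, was fixed before the data were examined. It assumed that reads with several genome positions could be shared between them. The table gives only 1 position, so each sequence was counted where the table puts it, and reads with 1 genome position were analysed apart. Of the 24 to 30 nt reads, 71.5% had 1 genome position, but only 17.4% of those on young LINE1 (L1) and IAP families did.

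Mapped reads per library ranged from 5099241 to 10240106 in the IPs and from 15109900 to 21220585 in total small RNA. Reads of 24 to 30 nt, the size of piRNAs, ranged from 608029 to 3843953 in the IPs. Sequencing reads after PCR without molecular identifiers are not independent molecules, so intervals given here cover counting error only. Between replicates, the counts per repeat feature varied 2.93 to 16.1 times more than counting error (chi-square per degree of freedom).

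Reads of 24 to 30 nt were summed per repeat family and strand relative to the element, which gave a sense and an antisense feature per family. Differences were tested with edgeR 4.0.16 (TMM scaling, filterByExpr defaults, glmQLFit and glmQLFTest) in R 4.3.3, in 1 fit of the 8 IP libraries, and in 1 fit of all 11 libraries for total small RNA, where the single Exd1+/- library borrows its spread from the other groups. The Benjamini-Hochberg adjusted p had to be under 0.05. The contrasts were genotype in MIWI2 IP, genotype in MILI IP, the difference between these, MIWI2 against MILI IP in Exd1+/-, and genotype in total small RNA. Genome loci were tested as 10 kb windows with reads of 1 genome position. Standard errors (SE) were derived from the test, as the absolute log2 fold change over the square root of its F statistic. Positive values are higher in Exd1-/- or in MIWI2 IP. Levels are CPM, the read count scaled by all 24 to 30 nt reads of the library, or for windows by those with 1 genome position.

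On simulated data with known changes, the test recovered 54.5% of 1.5-fold and 83.3% of 4-fold changes in MIWI2 IP, 67.7% and 100.0% in MILI IP, and 49.2% and 93.9% in total small RNA. For 10 kb windows it recovered 0% of 1.5-fold and 42.9% of 4-fold changes. Between 2.86% and 7.22% of the calls on simulated data were false. Features were simulated independently of each other and without a shift in background between genotypes, so this share need not hold for the real calls.

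The fixed lists were young L1, older L1, IAP, other ERVK, ERV1 with ERVL, MaLR and SINE families, each with its sense and its antisense features apart. A further list held the sense fragments of structural RNA (rRNA, tRNA, snRNA, scRNA, srpRNA), which are not piRNAs and were listed as a measure of background in an IP. That made 15 lists. They were tested with camera (limma 3.58.1) at its preset correlation of 0.01 and with an estimated correlation, and with fry. A list of 20 piRNA pathway genes and lists of marker miRNAs for germ cells, gonadal soma, muscle and mesenchyme, endothelium, blood, epithelium and broad expression were also fixed. Named features are up to 8 in each direction per contrast by log2 fold change, with an adjusted p under 0.05, a mean of at least 50 CPM and no overlap between the groups (no order rule for the difference), the 3 members with most reads of each list, 5 windows in each direction, and the 5 reporter positions with most reads per strand and library. Genes were tested per gene on 24 to 30 nt reads sense to exons, an analysis chosen after seeing the data. The genes named are those with at least 50 CPM that passed in the same direction with TMM, with library size alone and with DESeq2.

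The ping-pong signature was measured as the percent of 24 to 30 nt reads whose 5′ end lies opposite the 5′ end of another read with a 10 nt overlap. Libraries were thinned to 608029 reads, and the background was the mean over overlaps of 5 to 9 and 11 to 15 nt. Because the table gives 1 position per sequence, partners on different copies of a repeat are missed, and an overlap by sequence within a repeat family was added after seeing the data. Planted pairs at 30% were found at 30%. Percentages were compared by exact permutation tests, two-sided, whose smallest possible p with 2 against 2 libraries is 0.33, so they are given with their standard deviations (SD). Shares of a single library are given with exact Clopper-Pearson 95% intervals.

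Alternatives were library size alone, DESeq2 1.42.0, no filter, reads with 1 genome position, all lengths, a fit of the 4 libraries compared, the replicate number as a block, windows of 5 and 50 kb, distinct sequences, and each library left out. Transposon reads alone, a fit of the 3 total small RNA libraries, and the alternatives for genes, were chosen after seeing the data. Processing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and pyarrow 21.0.0, and figures used matplotlib 3.10.9. The reference annotation supplied was on another build and served only for gene name synonyms. The annotation in the table held no gene under the name of the Rosa26 locus. The counts of changed features were not set against other splits of the samples, since 2 against 2 libraries leave only 2 others. In total small RNA the ratio of piRNA-sized to miRNA-sized reads had no test, with 1 library in a group.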

Results

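The data describe small RNAs of newborn mouse testis, in which MILI and MIWI2, 2 PIWI proteins, carry piRNAs that guide silencing of transposons. MILI is mainly cytoplasmic and MIWI2 enters the nucleus. EXD1 is a protein with an exonuclease-like domain. The design compares Exd1-/- with Exd1+/- testes in MILI IP and in MIWI2 IP, with 2 libraries per genotype and antibody, and in total small RNA, with 1 Exd1+/- and 2 Exd1-/- libraries. A reporter with piRNA binding sites was sequenced from 1 MILI and 1 MIWI2 IP.

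The MILI IP libraries held 10240106 and 9384848 mapped reads in Exd1+/- and 7630814 and 7569045 in Exd1-/-. The MIWI2 IP libraries held 7016516 and 6298562 in Exd1+/- and 5099241 and 5348043 in Exd1-/-. Total small RNA held 15109900 reads in Exd1+/- and 21220585 and 20045578 in Exd1-/-. Reads of 24 to 30 nt made up 37.5% and 35.7% of MILI IP in Exd1+/- and 29.5% in both Exd1-/- libraries. They made up 25.5% and 21.3% of MIWI2 IP in Exd1+/- and 15.8% and 11.4% in Exd1-/-. In their place, reads of 12 to 19 nt took 77.0% and 82.4% of MIWI2 IP in Exd1-/- against 64.4% and 69.6% in Exd1+/-, and 59.9% and 60.1% of MILI IP against 51.6% and 53.6%. The most common length in 24 to 30 nt was 26 nt in MILI IP and 28 nt in MIWI2 IP in both genotypes.

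The knockout target Exd1 itself left few reads in these libraries. Exons of Exd1 had 75 and 42 sense reads of 24 to 30 nt in MILI IP of Exd1+/- and 34 and 38 in Exd1-/-, with at most 3 in any MIWI2 IP library. In MILI IP these were 19.5 and 12.5 CPM in Exd1+/- and 15.1 and 17.0 CPM in Exd1-/-. The tested difference there was -0.39 ± 0.25 (SE; adjusted p = 0.64), and -0.01 with library size alone. Small RNA reads do not show whether the stop codon cassette in exon 8 ended the protein. Of 20 piRNA pathway genes, 16 were annotated and 7 had enough sense exon reads to test, among them Piwil2, which encodes MILI, and Mael. With edgeR, 0 of the 7 changed in either IP or in the difference, over all genes or adjusted over the list alone, and 0 with DESeq2. An unadjusted p under 0.05 was found for 1 of them in each of these 3 contrasts. In MIWI2 IP the 7 genes had few reads, with at most 8.22 CPM in any library. Their SE was 0.86 or more there and 0.90 or more for the difference, against 0.16 to 0.28 in MILI IP. The tests in MIWI2 IP and of the difference therefore could not decide whether these genes changed. With library size alone, which moved the median of all genes in MILI IP from 0.00 to 0.38, Mov10l1 (0.98) and Mael (0.54) passed there, and Dnmt3l (0.60) over the list alone.

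In Exd1+/- testes, the comparison of MIWI2 with MILI IP asks which piRNAs are carried by which protein. Antisense piRNAs of young L1 families and of the IAP element IAPEz-int, active retrotransposons in mouse, were higher in MIWI2 IP. Antisense reads were higher in MIWI2 IP by 5.32 ± 0.10 (log2, SE; n = 2 libraries per IP) for L1Md_A, 5.30 for L1Md_Gf, 4.90 for L1Md_T, 4.55 for L1Md_F2, 5.04 for IAPEz-int, 4.85 for RLTR4_Mm and 4.67 for MERVL-int. The difference was smaller for the IAP families IAPEY3-int antisense (1.18) and IAPEy-int antisense (0.74), and the IAP antisense list, which was not tested here, took 5.63% of the reads in MIWI2 and 2.01% in MILI IP. Sense IAPLTR3 reads were higher by 5.16. Lower in MIWI2 IP were 5S RNA (-2.65 ± 0.15), U3 (-2.43), U1 (-1.62) and the satellites MurSatRep1 (-2.20) and MMSAT4 (-1.97), while LSU-rRNA_Hsa sense (1.47) and the satellite GSAT_MM sense (3.74) were higher. Structural RNA as a whole took 3.21% of the reads in MIWI2 and 2.03% in MILI IP. Antisense MYSERV6-int (-1.49) and MurERV4-int (-1.47) and sense ORR1E-int (-1.45, but 0.03 with reads of all lengths) were also lower in MIWI2 IP. Transposons took 68.3% ± 1.55 (SD, n = 2) of the 24 to 30 nt reads in MIWI2 IP and 36.0% ± 0.83 in MILI IP. Of 1278 features, 901 differed, 444 higher and 457 lower in MIWI2 IP (edgeR; adjusted p of IAPEz-int antisense 9.0e-13). Scaling by library size alone moved the median of all features from -0.19 to -0.70 and gave 334 higher and 748 lower, and DESeq2 gave 435 and 290. Reads of 1 genome position gave 1.56 for RLTR4_Mm antisense and 2.79 for L1Md_F2 antisense, and all lengths 2.62 for L1Md_F2 and 3.53 for L1Md_A antisense.

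In MILI IP, the genotype comparison asks what loss of EXD1 changes in the small RNAs recovered with MILI. Sense piRNAs of young L1 families, the strand of the L1 transcript itself, fell in Exd1-/- for 5 of 6 families. L1Md_A fell by 0.997 ± 0.096 (log2, SE; n = 2 per genotype; adjusted p = 1.6e-04), and L1Md_T (-0.79), L1Md_Gf (-0.78), L1Md_F2 (-0.73) and L1Md_F (-0.56) also fell, while L1Md_F3 was 0.01 ± 0.09 (-0.40 with reads of 1 genome position). Their share of the reads was 0.763% ± 0.0016 (SD) in Exd1-/- and 1.20% ± 0.15 in Exd1+/-, in libraries with 59.9% and 60.1% against 51.6% and 53.6% of reads at 12 to 19 nt. The ERVL element MERVL-int fell on both strands (sense -0.97 ± 0.07, adjusted p = 1.6e-05, and antisense -0.76), and sense MTA_Mm-int (-0.76) and the sense strand of the satellite GSAT_MM (-1.47 ± 0.31) also fell. Sense fragments of tRNA-Gln-CAA (1.26 ± 0.26), tRNA-Gln-CAG (1.14), tRNA-Pro-CCG (0.91), tRNA-Lys-AAG (0.81, but -0.03 with reads of 1 genome position) and tRNA-Asn-AAC (0.67) rose, as did 5S RNA (0.74 ± 0.12), antisense MLT1L (0.48) and sense IAPLTR3-int (0.45).

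**Figure D1:**
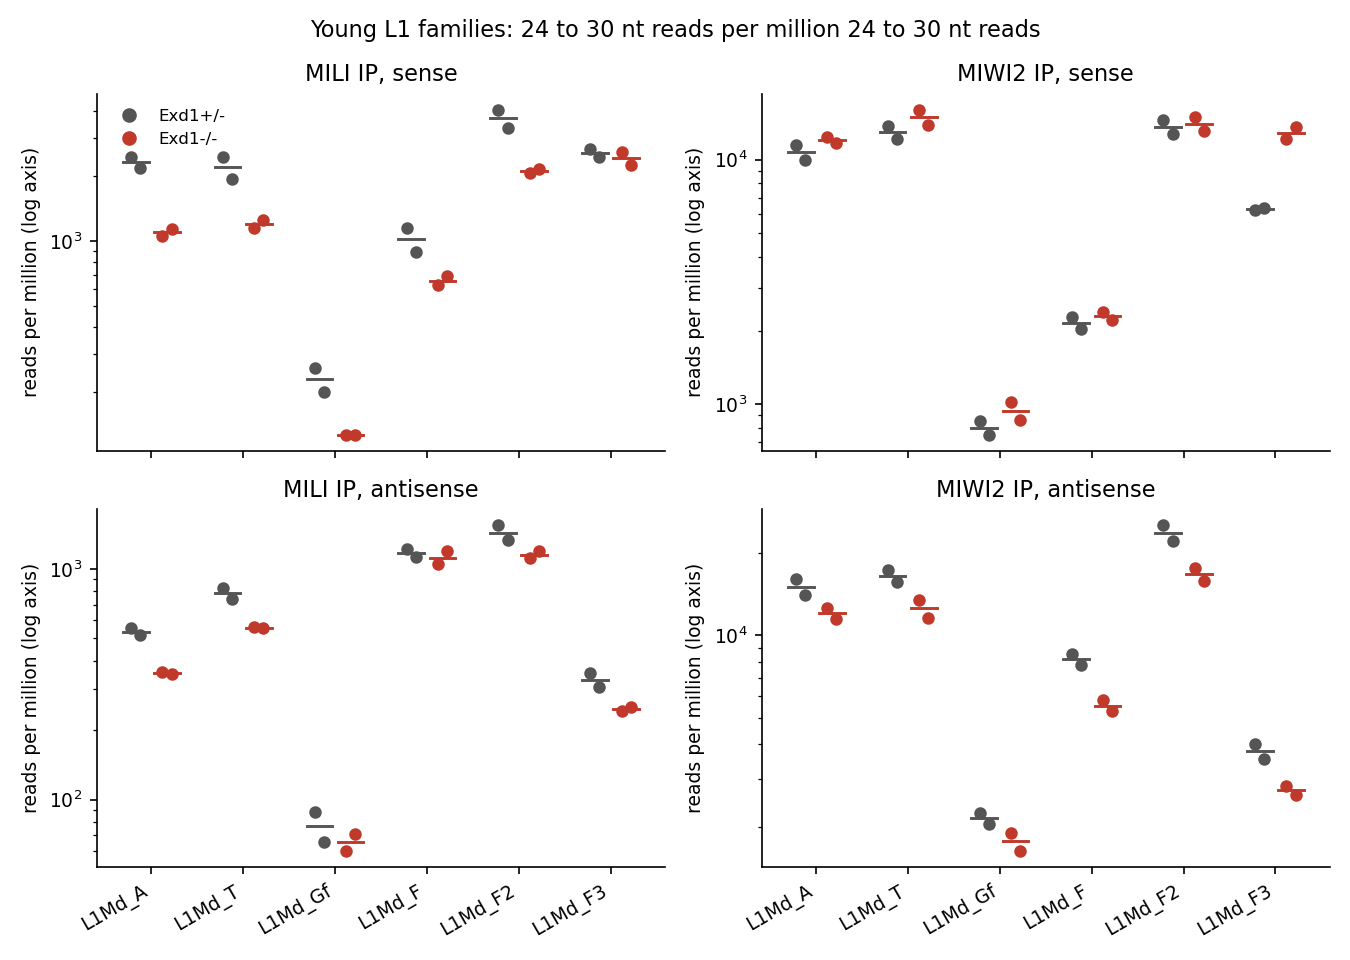
Reads of 24 to 30 nt on 6 young L1 families per library, as CPM on log axes, by IP, strand and genotype, with a line at the mean of 2 libraries. Sense reads in MILI IP were lower in Exd1-/- for 5 families (log2 change -0.997 for L1Md_A; median -0.75, and -0.18 with reads of 1 genome position), and sense L1Md_F3 reads were higher in MIWI2 IP (1.18, but -0.03 with reads of 1 genome position).

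Of 1278 features in MILI IP, 99 changed, 14 up and 85 down. With reads of all lengths the balance turned: 69 changed, 42 up and 27 down, and 28 of these were shared with the 99. The young L1 sense list fell with 5 of 6 members (5 adjusted over the list alone; median -0.75; camera adjusted p = 4.8e-11, and adjusted p = 0.254 with an estimated correlation). Sense ERV1 and ERVL families fell with 5 of 12 members (7 adjusted over the list alone; median -0.21; adjusted p = 4.5e-07, and 0.254 with an estimated correlation). Structural RNA rose with 8 of 51 members against 1 that fell (11 and 1 adjusted over the list alone; median 0.27; adjusted p = 4.5e-07, and 0.618 with an estimated correlation). A further 4 list calls were small and downward: young L1 antisense with 3 of 6 members (3 adjusted over the list alone; median -0.29), older L1 antisense with 4 of 22 (5; -0.17), ERV1 and ERVL antisense with 2 of 12 (4; -0.09), and other ERVK sense with 4 of 63 (1 up and 14 down; -0.08). Their adjusted p was 0.0066, 0.0066, 0.033 and 0.033, and 0.618 for each with an estimated correlation. The remaining lists had no call. IAP sense had 1 up and 1 down of 16 (1 and 1 adjusted over the list alone), IAP antisense 5 down (5), older L1 sense 3 of 22 down (3), SINE sense 4 of 26 down (5), SINE antisense 3 down (5), other ERVK antisense 3 of 63 down (2), MaLR sense 13 of 90 down (13) and MaLR antisense 2 up and 10 down of 89 (3 and 12). For SINE and MaLR sense reads the median was 0.00 and 0.02 while the mean was -0.08 and -0.04. IAP sense had a median of 0.03, and -0.05 with library size alone.

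The MILI IP count rested on single libraries: it was 28 without Exd1+/- library 1, 34 without Exd1-/- library 1 and 40 without Exd1-/- library 2, and it was 39 with reads of 1 genome position, 151 with library size alone (10 list calls in place of 7, with SINE antisense, IAP antisense and older L1 sense gained) and 171 in a fit of the 4 MILI libraries. L1Md_F sense did not pass without Exd1+/- library 1 (adjusted p = 0.098) or without Exd1-/- library 1 (0.12) or 2 (0.054), and of the 8 named rises 3 passed without Exd1+/- library 1 (adjusted p of the others 0.057 to 0.096), 6 without Exd1+/- library 2 (0.086 and 0.13), 1, which was no structural RNA, without Exd1-/- library 1 (0.057 to 0.23), and 4 without Exd1-/- library 2 (0.055 to 0.065), with MLT1L lost in each case. GSAT_MM did not pass without either Exd1-/- library (0.062 and 0.18). With reads of 1 genome position 1 of the 6 young L1 sense families passed (median -0.18). This was L1Md_F3 (-0.40), which stood at 0.01 in the main test. None of the young L1 sense families that fell in the main test passed with these reads.

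In MIWI2 IP, the same comparison asks what loss of EXD1 changes in the small RNAs recovered with MIWI2. Sense fragments of structural RNA, listed as a measure of background, rose in Exd1-/- for 21 of 51 members. Sense piRNAs of IAP families rose for 12 of 16, and antisense piRNAs of older L1 families fell for 16 of 22. As lists, each of the 3 had an adjusted p = 0.354 with an estimated correlation. Structural RNA took 7.82% ± 1.49 (SD, n = 2) of the 24 to 30 nt reads in Exd1-/- and 3.21% ± 0.48 in Exd1+/-. In the same libraries, reads of 12 to 19 nt took 77.0% and 82.4% against 64.4% and 69.6% of all mapped reads. IAP sense reads took 4.05% ± 0.039 and 2.76% ± 0.083, antisense older L1 reads 2.71% ± 0.21 and 4.36% ± 0.36, and antisense young L1 reads 5.13% ± 0.41 and 6.92% ± 0.57. The fragments that rose included tRNA-Lys-AAA (1.84 ± 0.20, SE; adjusted p = 1.1e-04), tRNA-Lys-AAG (1.67), tRNA-Pro-CCG (1.66), tRNA-Gln-CAG (1.66), tRNA-Asp-GAY (1.55), tRNA-Asn-AAC (1.52), tRNA-Gln-CAA (1.51) and 5S RNA (1.45). The IAP coding element IAPEz-int rose on the sense strand by 1.11 ± 0.08 (adjusted p = 2.1e-05; 0.18 with reads of all lengths, adjusted p = 0.38), and IAPEY3-int (0.43) and IAPEy-int (0.34) rose less. GSAT_MM fell on both strands (sense -2.03 ± 0.31, antisense -1.51). Sense RMER17A2 (-1.12), RMER17B (-1.01 ± 0.09, adjusted p = 3.9e-05) and RMER17D2 (-1.01) and antisense Tigger15a (-1.08), MusHAL1 (-1.01) and RLTR44C (-0.98) also fell.

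**Figure D2:**
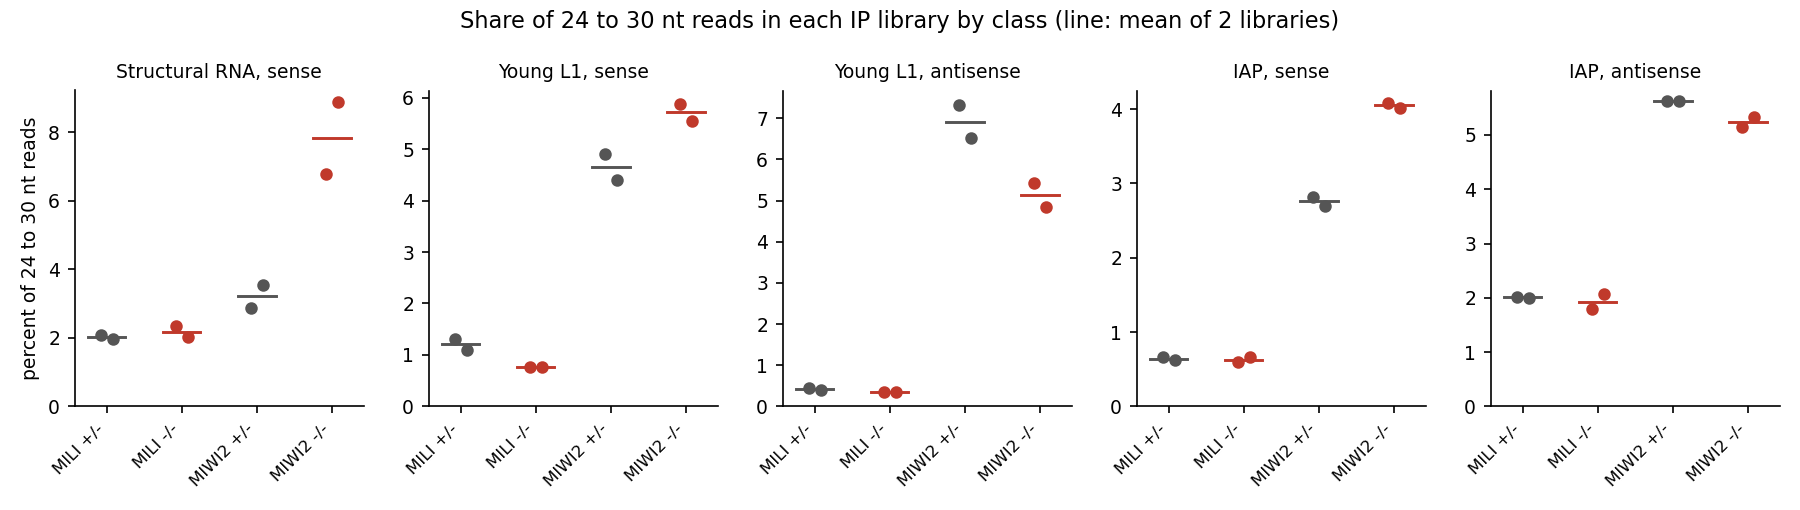
Percent of the 24 to 30 nt reads of each IP library on structural RNA, young L1 and IAP elements by strand, with a line at the mean of 2 libraries. In MIWI2 IP, structural RNA was 7.82% in Exd1-/- and 3.21% in Exd1+/-, and antisense young L1 was 5.13% and 6.92%.

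Of 1278 features in MIWI2 IP, 270 changed, 109 up and 161 down. Structural RNA rose with 21 of 51 members (25 adjusted over the list alone; median 1.15; camera adjusted p = 3.2e-18, and adjusted p = 0.354 with an estimated correlation). IAP sense rose with 12 of 16 (12 adjusted over the list alone; median 0.44; adjusted p = 3.0e-08, and 0.354 with an estimated correlation). Older L1 antisense fell with 16 of 22 (1 up and 16 down adjusted over the list alone; median -0.55; adjusted p = 2.7e-10, and 0.354 with an estimated correlation), with L1VL4 at -0.86 and L1_Mus1 at -0.32 as members with many reads. Young L1 sense rose with 3 of 6 (4 adjusted over the list alone; median 0.33; adjusted p = 4.2e-04, and 0.354 with an estimated correlation). The members were L1Md_F3 (1.18 ± 0.10, adjusted p = 2.4e-05), L1Md_Gf (0.38) and L1Md_A (0.31 ± 0.09, adjusted p = 0.034). Young L1 antisense fell with 3 of 6 (4; median -0.29), namely L1Md_F (-0.43), L1Md_F2 (-0.36) and L1Md_F3 (-0.34), and SINE antisense with 6 of 26 (10; -0.15), among them B2_Mm2 (-0.37). Both lists had an adjusted p of 0.021, and of 0.568 and 0.617 with an estimated correlation. The other 9 lists had no call. Adjusted over the list alone, they had 2 up and 3 down for SINE sense, 10 and 21 of 63 for other ERVK on either strand, 4 and 3 for IAP antisense, 1 and 4 for older L1 sense, 2 of 12 down for ERV1 and ERVL sense, 1 and 5 for ERV1 and ERVL antisense, 6 and 11 of 90 for MaLR sense and 4 and 21 of 89 for MaLR antisense. Over all features the counts were 2 and 3, 7 and 17 (sense) or 16 (antisense), 2 and 2, 1 and 3, 2 down, 1 and 5, 6 and 11, and 4 and 21. MaLR sense had a median of 0.01 and a mean of -0.05, and IAP antisense a mean of 0.07, which was -0.07 with library size alone.

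Scaling by library size alone moved the median of all MIWI2 IP features from 0.02 to -0.12 and gave 70 up and 251 down, and 10 lists in place of 6. The 4 gained were other ERVK on both strands and the antisense ERV1 with ERVL and MaLR lists, all downward. DESeq2 gave 69 and 191, no filter gave 66 and 241, all lengths gave 338 and 393 with the named structural RNA changes between 0.43 and 0.76 (tRNA-Asp-GAY 0.43, adjusted p = 0.16), and the count was 173 without Exd1-/- library 2. For young L1, with library size alone 1 family passed, with reads of 1 genome position the median was -0.02, with all lengths 3 families fell and 1 rose (median -0.47), L1Md_A did not pass without Exd1+/- library 2 (adjusted p = 0.41) or without Exd1-/- library 1 (0.30) or 2 (0.067), L1Md_Gf did not pass without Exd1+/- library 2 (0.31) or Exd1-/- library 1 (0.43), and the antisense L1Md_F2 and L1Md_F3 falls did not pass without Exd1+/- library 1 (0.18 and 0.15) or Exd1-/- library 2 (0.12 and 0.077).

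The test of the difference between the 2 IPs asks which small RNA features changed with Exd1 loss differently by IP. The change of sense young L1 reads with Exd1 loss was higher in MIWI2 than in MILI IP for all 6 families: 5 fell in MILI IP, and 3 rose in MIWI2 IP (with reads of all lengths 1 rose and 3 fell there). The difference of the log2 changes was 1.31 ± 0.13 (SE; n = 2 per group) for L1Md_A (adjusted p = 3.3e-04), 1.18 for L1Md_F3, 1.15 for L1Md_Gf (-0.06 with reads of 1 genome position), 1.14 for L1Md_T, 0.91 for L1Md_F2 and 0.79 for L1Md_F. Of 51 structural RNA features, listed as a measure of background, 8 also differed (adjusted p = 0.519 for the list with an estimated correlation). Among them were small subunit rRNA at 1.47 ± 0.18 (adjusted p = 8.6e-04), tRNA-Lys-AAA at 1.38, large subunit rRNA at 1.32 and U6 at 1.29. IAPEz-int (1.07 sense, 0.34 with all lengths, adjusted p = 0.32, and 0.57 antisense), MERVL-int (1.12 sense, 0.27 with all lengths, adjusted p = 0.35, and 0.61 antisense) and MMETn-int (0.71 sense) differed the same way. In the opposite direction stood antisense Tigger15a (-0.97) and L1VL2 (-0.59) and sense L1MC4a (-0.91), RLTR9C (-0.91), RMER17D2 (-0.79), RMER17A2 (-0.72), RMER17B (-0.62) and RLTR10D (-0.62).

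Of 1278 features, 57 had different genotype effects in the 2 IPs, 45 higher and 12 lower in MIWI2 IP. Young L1 sense was called with 6 of 6 members (6 adjusted over the list alone; median 1.15; camera adjusted p = 2.3e-21, and adjusted p = 0.110 with an estimated correlation). Structural RNA had 8 of 51 (13; 0.60; 2.6e-09), IAP sense 4 of 16 (6; 0.21; 7.1e-06), and ERV1 and ERVL sense 3 of 12 (5 up and 1 down; 0.18; 0.0052), in the same order of count adjusted over the list alone, median and adjusted p, each with adjusted p = 0.519 with an estimated correlation. Older L1 antisense was lower with 2 of 22 (8; -0.30; 1.8e-06, and 0.519 with an estimated correlation), and IAP antisense higher with 2 of 16 (2; 0.19; 0.025, and 0.857 with an estimated correlation). No other list was called. SINE sense had 1 up (1 adjusted over the list alone), other ERVK sense 2 up and 3 down (3 and 3), other ERVK antisense 1 up (1), ERV1 and ERVL antisense 1 up (2), MaLR sense 3 up (1) and MaLR antisense 1 down, which did not pass over the list alone. With edgeR, 0 members passed for SINE antisense (1 at an unadjusted p under 0.05, 0 with DESeq2), young L1 antisense (2, and 1 with DESeq2; 1 down adjusted over the list alone) and older L1 sense (5, and 1 with DESeq2; 1 up and 1 down adjusted over the list alone). Medians and means differed in sign for young L1 antisense (0.01 and -0.01), MaLR sense (0.06 and -0.01) and MaLR antisense (-0.03 and 0.01), and camera gave a downward direction for older L1 sense at a median of 0.05.

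Library size alone gave 38 up and 21 down and no IAP antisense call (adjusted p = 0.080), DESeq2 37 and 29, no filter 25 and 39, reads of 1 genome position 16 and 37 with 20 of the features shared, and all lengths 30 and 46 with 10 shared; the young L1 sense median was 0.24 with 1 genome position, where none of the 6 families passed, and 0.38 with all lengths, where 1 of 6 passed. The count was 32 without MILI Exd1+/- library 1, 37 without library 2, 24 without MILI Exd1-/- library 1, 30 without MIWI2 Exd1+/- library 1, 86 without MIWI2 Exd1-/- library 1, and between 39 and 77 without any other; tRNA-Lys-AAA did not pass without MILI Exd1-/- library 1 (adjusted p = 0.075) or 2 (0.089) or MIWI2 Exd1+/- library 1 (0.051), and of the 8 lower features 1 passed without MILI Exd1+/- library 2 or MILI Exd1-/- library 1, 2 without MIWI2 Exd1+/- library 1, 4 without MIWI2 Exd1-/- library 2, 5 without MILI Exd1-/- library 2 and 6 without MILI Exd1+/- library 1.

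Read sequence and overlap ask how the piRNAs were made: a 5′ U marks primary piRNAs, and an A at position 10 with a 10 nt overlap marks the product of slicing by a partner piRNA (ping-pong). In MIWI2 IP, an A at position 10 was found in 34.4% ± 0.70 (SD, n = 2) of the 24 to 30 nt reads in Exd1-/- and 41.9% ± 0.011 in Exd1+/-, and a 5′ U in 71.3% ± 1.21 and 67.5% ± 1.08. In MILI IP, an A at position 10 was found in 24.6% ± 0.042 and 26.4% ± 0.19, and a 5′ U in 84.2% ± 0.12 and 83.7% ± 0.17. On antisense young L1 reads, the A at position 10 was 45.8% ± 0.73 and 55.2% ± 0.73 in MIWI2 IP and 25.6% ± 0.72 and 36.0% ± 0.34 in MILI IP. The antisense part of young L1 reads was 47.3% ± 0.98 in Exd1-/- and 59.8% ± 0.16 in Exd1+/- in MIWI2 IP, but 31.4% ± 0.96 and 26.5% ± 0.78 in MILI IP. For IAP it was 56.4% ± 0.79 and 67.1% ± 0.66 in MIWI2 IP and 75.5% and 75.8% in MILI IP. The 10 nt overlap on the genome was found for 2.06% ± 0.17 of MIWI2 reads in Exd1-/- and 2.62% ± 0.0092 in Exd1+/-, over a background of 0.835% and 0.854% against 0.895% and 0.986%. In MILI IP it was 0.589% ± 0.053 and 0.754% ± 0.064, over 0.265% and 0.226% against 0.294% and 0.305%. Over background, the MILI difference was -0.111 points (exact permutation p = 0.33), and -0.048 with reads of 1 genome position and -0.027 with distinct sequences, where the libraries of the genotypes overlapped (exact permutation p = 0.67). Against MILI reads of Exd1+/-, 5.26% ± 0.031 and 6.21% ± 0.23 of MIWI2 reads had a partner, over a background between 2.71% and 2.90% in the 4 libraries. Only the Exd1+/- reads were thus matched to their own genotype, and partners in Exd1-/- MILI IP were not counted. By sequence within young L1 families, 4.95% ± 0.31 of MILI reads in Exd1-/- and 12.1% ± 1.24 in Exd1+/- had a partner in their own library, and 26.9% ± 1.004 and 31.1% ± 0.41 of MIWI2 reads. The background of this measure was 1.89% and 1.95% against 3.71% and 3.52% in MILI IP, and 19.2% and 16.5% against 18.6% and 17.9% in MIWI2 IP. After thinning, MILI IP held 6699 and 6790 young L1 reads in Exd1-/- against 10765 and 9092, so fewer partners were possible. Over background, the MIWI2 difference was -5.73 points for antisense young L1 reads. For sense reads it was -0.199, and the libraries of the genotypes overlapped. Each of these differences in percent, except that of the MILI IAP strand, was larger than the SD of either group, with background and differences over background aside. The exact two-sided permutation test cannot go below 0.33 with 2 against 2 libraries. With reads of all lengths the 5′ U difference turned to -6.12 points in MIWI2 IP and -3.87 in MILI IP, and that of the A at position 10 was -3.48 (from -7.50) and -0.232 (from -1.76). In MIWI2 IP, the antisense part of IAP reads differed by -10.7 points, but by -4.64 with distinct sequences and -0.970 with all lengths, and that of young L1 reads by -12.5 and by -7.20 with distinct sequences.

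Windows of 10 kb ask which genome loci (mm9, reads of 1 genome position) fed MIWI2 differently. A window on chromosome 11, from 23110001 to 23120000, rose by 4.79 ± 0.38 (SE; adjusted p = 1.7e-12), from 10.6 and 1.53 CPM in Exd1+/- to 205 and 196 in Exd1-/-; 38.3% of its reads had no annotation and 25.5% were antisense to the L1 family Lx8. Another on chromosome 7, from 107660001 to 107670000, fell by 4.48 ± 0.40 (adjusted p = 8.0e-11), from 162 and 150 to 7.89 and 6.98 CPM, and 85.3% of its reads were sense to B2_Mm1a. Windows on chromosome 9 from 87080001 (-2.32; RLTR44A and RLTR44-int antisense), chromosome 13 from 49930001 (-2.26; 86.9% Lx antisense), chromosome 15 from 38540001 (-2.10; 74.2% IAPEz-int antisense) and chromosome 9 from 103250001 (-2.10; 99.0% exon sense of Cdv3) also fell. On chromosome 4 the windows from 128720001 (2.58 ± 0.42) and 128640001 (2.26 ± 0.51) rose, as did that on chromosome 2 from 35860001 (1.87). The window from 128640001 stood at 8.27 and 234 CPM in Exd1+/- and 352 and 852 in Exd1-/-, and its change was 1.08 without Exd1+/- library 1 and 5.89 without library 2. The highest change, 9.97 ± 1.03 on chromosome 9 from 67550001 (97.9% L1M2 antisense), came from 1 library, with 3111 CPM in Exd1-/- library 2 and 23.7 in library 1. Of 31512 windows, 586 changed, 159 up and 427 down; without Exd1-/- library 2 the count was 256, and the windows from 67550001 (3.95, adjusted p = 0.095) and 128720001 (1.07, adjusted p = 0.45) did not pass. Library size alone moved the median of all windows from -0.08 to 0.03 and gave 263 up and 299 down, and the replicate number as a block gave 886 windows. In MILI IP all named windows but that from 67550001 moved the same way, though not all as far. There the chromosome 11 window stood at 4.44 and 6.85 CPM in Exd1+/- and 65.7 and 100 in Exd1-/-. The chromosome 13 window stood at 27.6 and 18.7 in Exd1+/- and 5.26 and 7.44 in Exd1-/-. The chromosome 7 window fell less in MILI IP, from 25.7 and 28.1 to 19.5 and 14.3. That on chromosome 15 stood at 8.57 and 9.37 in Exd1+/- and 2.63 and 7.97 in Exd1-/-. The difference between the IPs was not tested on windows.

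Total small RNA asks whether the piRNA pool as a whole changed, with 1 Exd1+/- library. Antisense young L1 piRNAs fell in both Exd1-/- libraries: L1Md_A by 1.45 ± 0.10 (log2, SE; adjusted p = 2.2e-07), L1Md_F2 -1.38, L1Md_T -1.34, and on the same strand L1Md_F3 antisense -1.26, L1Md_F antisense -1.21 and L1Md_Gf antisense -1.19. Per 1000 miRNA reads, antisense young L1 reads numbered 13.4 in Exd1+/- and 4.66 and 4.37 in Exd1-/-, sense young L1 reads 9.89 against 6.45 and 6.10, antisense older L1 reads 8.28 against 5.03 and 4.91, and antisense IAP reads 8.61 against 5.36 and 5.19. Antisense MusHAL1 (-1.82), L1VL4 (-1.37), L1VL2 (-1.36) and RLTR44C (-1.64), MTA_Mm-int (-0.99), IAPEz-int antisense (-0.87), MERVL-int (-0.77 sense, -0.83 antisense) and GSAT_MM (-2.13 ± 0.41) also fell. Sense L1Md_A (-0.67) and L1Md_Gf (-0.86) fell, and sense L1Md_F3 rose by 0.35 (adjusted p = 0.032), but was -0.02 with library size alone and -0.48 with reads of 1 genome position. U1 (1.52), U6 (1.36), small subunit rRNA (0.99), large subunit rRNA (0.88), 5S RNA (0.78) and RMER17A2 (1.35) rose. U1 stood at 915 CPM in Exd1+/- and 2887 and 1150 in Exd1-/- and was 0.67 without Exd1-/- library 1, and U6 was 0.40 with reads of 1 genome position (adjusted p = 0.33). With library size alone, small subunit rRNA was 0.62, large subunit rRNA 0.51 and 5S RNA 0.41. Reads without annotation numbered 83.3 per 1000 miRNA reads in Exd1+/- and 134 and 138 in Exd1-/-. The ratio of 24 to 30 nt to 21 to 23 nt reads was 0.470 in Exd1+/- and 0.491 and 0.494 in Exd1-/-. The direction turned for 26 to 28 over 22 nt reads (0.494 against 0.448 and 0.471) and for distinct sequences (3.56 against 2.94 and 3.14).

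**Figure D3:**
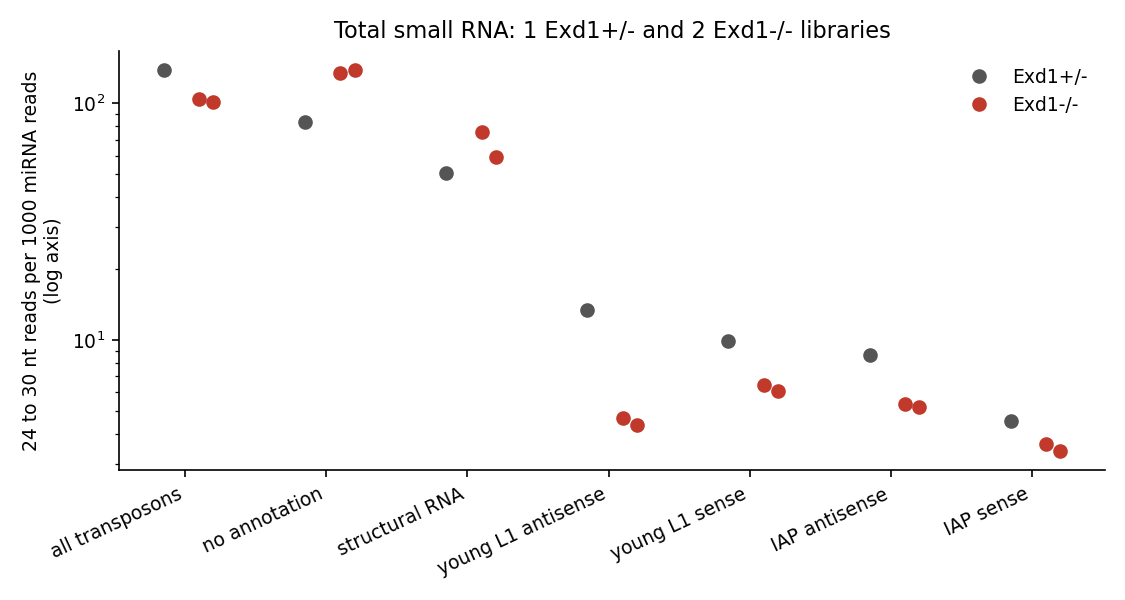
Reads of 24 to 30 nt per 1000 miRNA reads by class on a log axis, in 1 Exd1+/- and 2 Exd1-/- total small RNA libraries. Antisense young L1 reads were 13.4 in Exd1+/- and 4.66 and 4.37 in Exd1-/-.

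Of 1374 features in total small RNA, 448 changed, 212 up and 236 down. Scaling by library size alone moved the median from 0.03 to -0.34 and gave 135 up and 463 down, and scaling to 21 to 23 nt reads moved it to -0.28 and gave 129 and 361; the falls of young L1 antisense were larger than these shifts. The Exd1+/- group has no replicate, so each SE and p here takes its spread from the other groups and covers no difference between Exd1+/- pools. The 2 Exd1-/- libraries, which varied 16.1 times more than counting error, gave that spread alone in a fit of 3 libraries, where 458 features passed and L1Md_A antisense was -1.46 ± 0.10. Markers of other cells moved too, given as CPM of miRNA reads for Exd1+/- and then the 2 Exd1-/- libraries. The muscle miR-133a was 581, 7444 and 1372, while miR-1-1 was 0, 2.62 and 0.177 and all muscle and mesenchyme miRNAs were 44797, 40927 and 36840.0. Blood miR-451 was 419, 725 and 553 and miR-144 was 196, 595 and 342, with the blood list at 1118, 1905 and 1437. Germ cell and pluripotency miRNAs were 788, 820.1 and 849, and miR-202 of the gonadal soma was 5988, 7429.9 and 7017. Endothelial miRNAs were 24700, 19555 and 22404, epithelial miRNAs 8018, 6590 and 7363, and broadly expressed miRNAs 67375, 55735 and 59502.

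The reporter asks whether slicing of a transcript by piRNAs makes new piRNAs from it. It held 94181 reads in MILI IP and 174362 in MIWI2 IP, each from 1 library of unknown total depth. Sense reads, which come from the reporter transcript, made up 64.7% (95% interval 64.4 to 65.0) in MILI IP and 79.5% (79.3 to 79.7) in MIWI2 IP. Between the LoxP sites, at 687 to 720 and 3471 to 3504 of the reporter, lay 88.3% and 97.5% of sense reads, while the coding sequence from 1 to 678 held 9.41% and 1.73%. Of sense reads, 54.5% in MILI IP and 63.9% in MIWI2 IP had an A at position 10. Counting 24 to 30 nt reads only, the sense positions with most reads were 3300 (4160 reads), 1717 (2714), 1291 (2518), 1977 (2094) and 3147 (1823) in MILI IP and 2471 (11589), 1188 (10554), 1717 (8948), 1191 (6049) and 2772 (5244) in MIWI2 IP. The antisense position with most 24 to 30 nt reads was 971 in both, with 3214 reads in MILI IP and 6867 in MIWI2 IP. The next were 1726 (1507), 1424 (1221), 3309 (1102) and 1500 (842) in MILI IP and 1424 (1177), 1500 (934), 3309 (821) and 3008 (481) in MIWI2 IP. Of antisense reads, 95.1% and 93.1% had the sequence of a read in the table of the Exd1 libraries, against 0.617% and 3.44% of sense reads. With each distinct sequence counted once, these were 61.9% and 52.8% of antisense and 2.12% and 3.99% of sense sequences. An A at position 10 was then found in 28.8% and 29.7% of sense sequences, and the coding sequence held 13.8% and 6.11% of them.

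**Figure D4:**
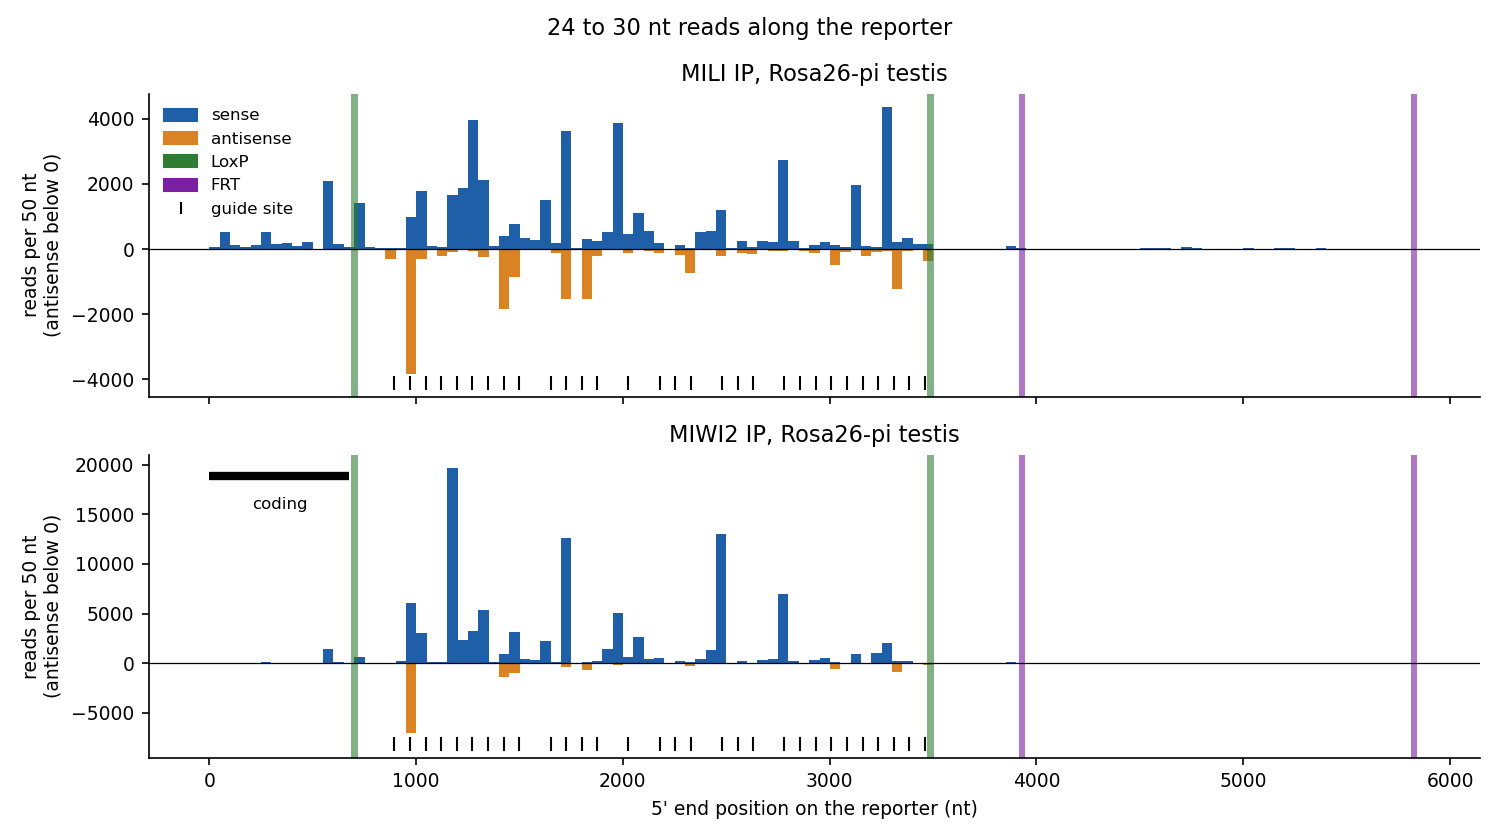
Counts of 24 to 30 nt reads per 50 nt along the reporter by 5′ end (sense above 0, antisense below), with the LoxP and FRT sites and the 30 guide sites. Of the sense reads of this size, 89.2% in MILI IP and 97.5% in MIWI2 IP lay between the LoxP sites.

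Guide sites were 30 positions with at least 50 antisense reads of 24 to 30 nt over both IPs. Only reads whose sequence was in the table of the Exd1 libraries counted. They were chosen after the data were seen, where the labels give 35 binding sites. At least 1 sense 24 to 30 nt read began at the position sliced under a guide at 29 sites in MILI IP and 28 in MIWI2 IP. Some held few, with 1 read in MILI IP under the guide at 3460 and 4 in MIWI2 IP at 1804. Other positions with such a read were not counted. Between MILI antisense reads at a guide and sense reads at its slice, the Spearman correlation was 0.22 in MILI IP and 0.17 in MIWI2 IP. Slice positions, 1.09% of those between the LoxP sites, began 30.5% of sense reads in MILI IP and 52.4% in MIWI2 IP. A 10 nt overlap with antisense reads of MILI IP was found for 50.5% of MILI sense reads (background 18.6%) and 67.3% of MIWI2 sense reads (background 21.8%), and with antisense reads of MIWI2 IP for 68.6% (25.5%) and 76.1% (25.8%). With each distinct sequence counted once, these shares were 19.2% (background 11.6%) and 22.4% (13.9%) with MILI partners and 24.8% (15.7%) and 29.01% (19.1%) with MIWI2 partners. No Exd1-/- library was made with the reporter, so these data hold no comparison by genotype.

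**Figure D5:**
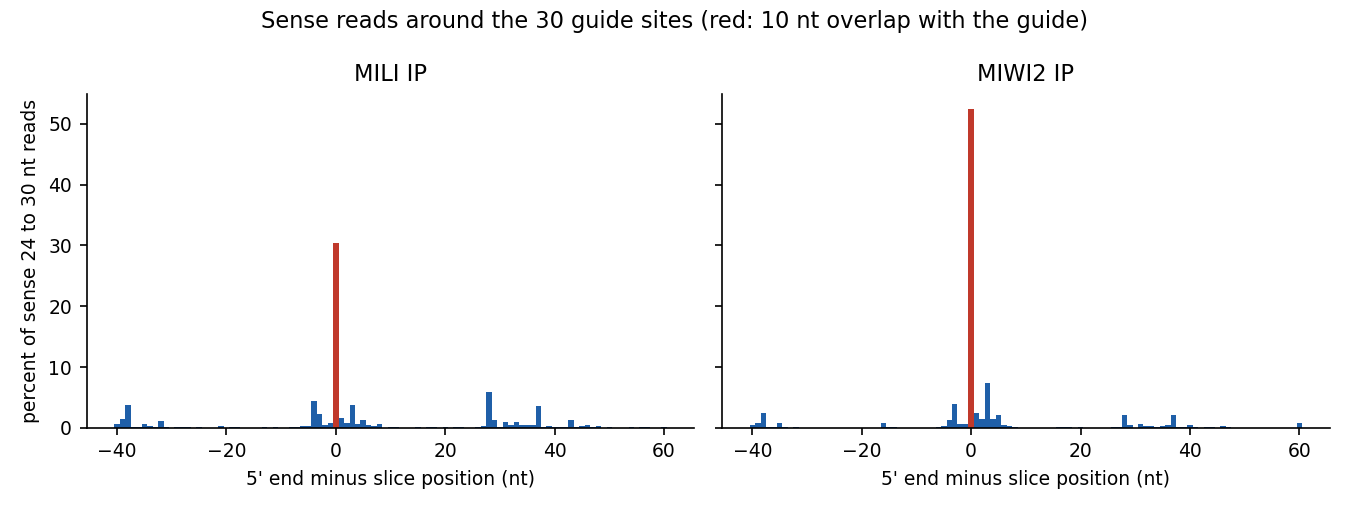
Percent of sense 24 to 30 nt reporter reads by the distance in nt of their 5′ end from the position sliced under the 30 guide sites. The bar at 0 holds 30.5% of reads in MILI IP and 52.4% in MIWI2 IP.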

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

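The tests of background on young L1 reads, and those of germ cells and of yield in total small RNA, were chosen only after the result was seen. The effect of Exd1 loss differed between MIWI2 and MILI IP for 57 of 1278 features, by a test of the difference itself with 2 libraries per group. The log2 differences, MIWI2 minus MILI IP, were 1.31 for L1Md_A, 1.18 for L1Md_F3, 1.15 for L1Md_Gf and 1.14 for L1Md_T, all sense. For structural RNA they were 1.47 for small subunit rRNA, 1.38 for tRNA-Lys-AAA, 1.32 for large subunit rRNA and 1.29 for U6. In the other direction they were -0.97 for Tigger15a antisense, -0.91 for L1MC4a sense, -0.91 for RLTR9C sense, -0.79 for RMER17D2 sense, -0.72 for RMER17A2 sense, -0.62 for RMER17B sense, -0.62 for RLTR10D sense and -0.59 for L1VL2 antisense.

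Sense young L1 reads fell in MILI IP of Exd1-/- for 5 of 6 families, while 3 rose in MIWI2 IP, where the median was -0.02 and none passed with reads of 1 genome position, and 1 rose and 3 fell with all lengths. More background in the Exd1-/- MILI libraries would have lowered other sense transposon reads, whose median was -0.0843 (spread 0.209) with library size alone. Families that are themselves background would not fall, so this median could not exclude background. In these libraries miRNA reads per 1000 transposon reads were 1.39 and 1.86, against 0.569 and 0.905 in Exd1+/-. Transposons took 32.35% of the reads against 36.0%. Thinning to equal depth gave a median of -0.718 (spread 0.314), but random thinning keeps each share, so it could not test depth. Placement of reads with several genome positions was the same in all libraries, since each sequence had 1 position and 1 annotation. It could assign a change to the wrong family, but could not by itself differ between genotypes. With reads of 1 genome position the median was -0.179 (spread 0.128), within the limit of -0.2 set beforehand by less than its spread. Those reads are a small part of young L1 reads, so this median could not decide how much placement mattered. An effect of EXD1 loss on MILI piRNAs from L1 transcripts stays open as a hypothesis. These data cannot separate it from background or from changes of other families whose reads were placed on young L1.

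Antisense young L1 reads were lower in total small RNA of Exd1-/-, at 4.66 and 4.37 per 1000 miRNA reads against 13.4. Fewer germ cells would have lowered germ cell miRNAs. The lower of the 2 Exd1-/- over Exd1+/- ratios was 1.04 and the higher 1.08 (spread 0.036). Both ratios share the 1 Exd1+/- library, so this spread covers no difference between Exd1+/- pools. For unannotated 24 to 30 nt reads per miRNA read, the lower ratio was 1.61 (spread 0.0502), but such reads need not be piRNAs. Per 1000 miRNA reads, exon sense reads also rose, from 15.3 in Exd1+/- to 22.1 and 23.3 in Exd1-/-. Structural RNA reads rose from 50.7 to 75.8 and 59.2, and all transposon reads fell from 138 to 104 and 101. This ratio could therefore not test the yield of piRNAs, and a lower yield stays open. Muscle miR-133a and blood miRNAs also differed between these libraries, and a property of the single Exd1+/- library stays open. Loss of EXD1 is the biological difference of the design and stays a hypothesis.

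Structural RNA fragments rose in MIWI2 IP of Exd1-/-, from 3.21% to 7.82% of the reads, and reads of 12 to 19 nt were 77.0% and 82.4% of all mapped reads against 64.4% and 69.6%. Thinning to equal depth gave a median log2 change of 1.31 (spread 0.502), but random thinning keeps each share, so it could not test depth. Recovery of fewer piRNAs over the same background is a candidate explanation: miRNA reads per 1000 transposon reads, taken as a measure of background, were 1.34 and 2.40 in Exd1-/- and 0.857 and 0.748 in Exd1+/-, a log2 change of 1.22 (spread 0.599). The same measure was also higher in MILI IP of Exd1-/-, at 1.39 and 1.86 against 0.569 and 0.905. Structural RNA there took a mean of 2.18% of the reads in Exd1-/- and 2.03% in Exd1+/-, and 8 of its 51 members rose against 1 that fell (median 0.27). More broken RNA in these libraries and direct loading of such fragments on MIWI2 both stay open.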

How the results depend on the processing

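The alternatives for genes, the use of transposon reads alone and the fit of the 3 total small RNA libraries were chosen only after the data were seen; the cause of each change below was not tested unless given. Over 148 named features, another setting left 769 calls as they were, weakened 70, strengthened 21 and reversed 13, and leaving out a library left 521 as they were, weakened 94 and strengthened 5. The counts for MIWI2 against MILI IP in Exd1+/- and for total small RNA stayed within 1.5 times under every alternative run.

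The count of 270 changed features in MIWI2 IP was 731 with reads of all lengths and 173 to 274 with a library left out. The 99 in MILI IP were 151 with library size alone, 39 with reads of 1 genome position, 171 in a fit of 4 libraries and 28 to 81 with a library left out. The 57 that differed between IPs were 24 to 86 with a library left out. The 586 windows were 886 with the replicate number as a block and 256 to 734 with a library left out. Of genes, the 51 in MIWI2 IP were 20 to 44 with a library left out, the 75 in MILI IP were 20 with DESeq2, 443 with library size alone and 12 to 26 with a library left out, and the 11 for the difference were 4 with DESeq2, 4 with library size alone and 5 to 9 with a library left out. The list calls, 19 over the 3 contrasts, were 0 with an estimated correlation. With fry, which tests whether a list moves one way and not whether it differs from other features, 4 lists passed in MIWI2 IP, 3 in MILI IP and 1 for the difference, where camera called 6, 7 and 6. Scaled by library size alone, camera called 10, 10 and 5.

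Only values past the threshold in at least 1 of the 2 settings are counted as reversed. With all lengths in MIWI2 IP these were the sense changes of L1Md_A (-0.49), L1Md_F (-0.46), L1Md_F2 (-0.37) and L1Md_Gf (-0.50), and between IPs ORR1E-int (0.0304). Sense L1Md_T in MIWI2 IP turned from 0.35 to -0.53 and passed in neither setting. Reversed with reads of 1 genome position were L1Md_F3 (-0.0321) and L1Md_Gf (-0.11) in MIWI2 IP, tRNA-Lys-AAG (-0.0319) and L1Md_F3 (-0.40) in MILI IP, L1Md_Gf (-0.0563) for the difference and L1Md_F3 (-0.48) in total small RNA, all sense. Sense L1Md_F2 (0.18 to -0.20) and L1Md_F (0.23 to below 0) in MIWI2 IP changed sign and passed in neither. With library size alone, L1Md_F3 (-0.0207) and IAPEz-int (-0.27) sense reversed in total small RNA.

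The 10 nt overlap difference between genotypes in MIWI2 IP, -0.557 points, was -0.767 with reads of 1 genome position, -0.373 with distinct sequences and -2.05 with all reads. That in MILI IP, -0.165, was -0.0838 with distinct sequences and -0.881 with all reads, where libraries differ in depth. Against Exd1+/- MILI reads, -0.956 became -1.72 with reads of 1 genome position. With distinct sequences and all lengths, in that order, the difference in MIWI2 IP was 6.34 and -6.12 points for the 5′ U (3.79), -5.12 and -3.48 for the A at position 10 (-7.50), 0.052 and -1.75 nt for mean length (-0.040, and -0.111 to 0.031 with a library left out), -7.20 and -11.6 for antisense young L1 (-12.5) and -4.64 and -0.970 for antisense IAP (-10.7). In MILI IP it was 1.17 and -3.87 for the 5′ U (0.519), and -1.56 and -0.232 for the A at position 10 (-1.76). Mean length there (-0.043) was -0.957 nt with all lengths and -0.093 to 0.0072 with a library left out. Antisense young L1 in MILI IP (4.91) was 3.89 with distinct sequences, and antisense IAP (-0.288) was -0.732 to 0.155 with a library left out.

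The difference in the ratio of piRNA-sized to miRNA-sized reads, 0.022, was -0.035 for 26 to 28 over 22 nt and -0.522 with distinct sequences. On the reporter, with distinct sequences and with 24 to 30 nt reads in that order, the sense share was 73.4% and 74.7% in MILI IP (64.7%) and 74.2% and 87.8% in MIWI2 IP (79.5%), and the A at position 10 was 28.8% and 59.7% (54.5%) and 29.7% and 71.8% (63.9%). The MIWI2 IP libraries of Exd1-/- had the fewest 24 to 30 nt reads, 608029 in the lowest, and 42.9% of simulated 4-fold changes of 10 kb windows were recovered there.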

Other observations

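The tests per gene and the overlap by sequence were chosen only after the data were seen. Reads sense to exons of protein-coding genes also changed with Exd1 loss. In these fits the spread came almost wholly from all genes together. Each SE and p therefore hardly covers a gene's own difference between libraries. In MIWI2 IP, piRNA-sized reads fell for Cdv3 (-2.69 ± 0.25, log2, SE; adjusted p = 6.2e-24; n = 2 per genotype), Mid1, which encodes a ubiquitin ligase that binds microtubules (-2.25), 2210010C17Rik (-1.78) and Ppp2r5a, a regulatory subunit of protein phosphatase 2A (-1.50), and rose for G430022H21Rik (0.86 ± 0.15, adjusted p = 4.9e-06) and Mettl3, the RNA adenosine methyltransferase (0.72, adjusted p = 0.015). Mettl3 did not pass with any 1 MIWI2 library left out (adjusted p from 0.15 to 0.37), and Mid1 stood at 39.2 and 148 CPM in the 2 Exd1+/- libraries and was -1.28 without library 2. With library size alone, the MIWI2 changes were -1.93 for Cdv3, -1.54 for Mid1, -1.01 for 2210010C17Rik, -0.74 for Ppp2r5a, 1.64 for G430022H21Rik and 1.499 for Mettl3. In MILI IP, 2210010C17Rik fell (-0.89 ± 0.15, adjusted p = 1.9e-06), and the histone genes Hist1h4d (0.87), Hist1h1a (0.52) and Hist1h4k (0.51) and Klhl11 (0.58) rose. With library size alone these were -0.52 for 2210010C17Rik, 0.89 for Hist1h1a, 0.88 for Hist1h4k and 0.96 for Klhl11. Hist1h4d did not pass without Exd1+/- library 2 (0.56, adjusted p = 0.30), and Hist1h1a, Hist1h4k and Klhl11 did not pass with any 1 MILI library left out (adjusted p from 0.15 to 0.50). G430022H21Rik differed between the IPs by 1.25 ± 0.22 (adjusted p = 2.0e-05), but did not pass without MILI Exd1-/- library 2 (1.02, adjusted p = 0.068).

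Of 4316 genes, 51 changed in MIWI2 IP (3 up, 48 down), 75 in MILI IP (13 up, 62 down) and 11 in the difference (1 up, 10 down). With library size alone they split into 30 up and 11 down, 433 and 10, and 3 and 1, and with DESeq2 into 7 and 36, 4 and 16, and 1 and 3, so that no overall direction is given for genes. Library size alone moved the median of all genes to 0.56 in MIWI2 IP, 0.38 in MILI IP and 0.29 for the difference. The MIWI2 IP count was 25 without Exd1+/- library 1 and 20 without Exd1-/- library 2. The MILI IP count was 19 and 26 without Exd1+/- library 1 and 2 and 20 and 12 without Exd1-/- library 1 and 2. The difference count was 7 without MILI Exd1+/- library 1, 5 without MIWI2 Exd1+/- library 1, and 6 and 5 without MIWI2 Exd1-/- library 1 and 2.

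Among list members with many reads not described so far, the ERVK element MMERVK10C-int rose in MIWI2 IP on both strands (sense 0.54, adjusted p = 0.0019; antisense 0.41, adjusted p = 0.0042), and MTC fell on both (antisense -0.48, sense -0.28). By sequence within families, the 10 nt overlap in the same library was 3.93% ± 0.19 (SD, n = 2) of IAP reads in MILI IP of Exd1-/- and 5.13% ± 0.54 in Exd1+/-, and 35.3% ± 1.25 and 34.1% ± 0.010 in MIWI2 IP, over a background between 1.05% and 1.75% in MILI IP and between 15.2% and 16.6% in MIWI2 IP. For all transposons it was 3.80% ± 0.53 and 5.63% ± 0.39 in MILI IP and 23.9% ± 0.67 and 25.6% ± 0.43 in MIWI2 IP, over a background between 1.58% and 2.50% and between 12.004% and 12.96%.

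Of the sequences most read as antisense guides at the 30 reporter sites, 15 had 1 genome position, and 12 of these lay on chromosome 7 between 6567816 and 6600713 (mm9). By their annotation 18 were LTR, 7 LINE and 5 SINE sequences, 15 sense and 15 antisense to their repeat.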
